A study of Mus musculus with 6 samples.

How the data were processed

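RNA was measured by sequencing in liver samples of adult C57BL/6 mice, 3 from wild type mice and 3 from mice lacking Igfbp7, the gene for insulin-like growth factor binding protein 7. Per the labels' protocols, the knockout was made with Cre-loxP recombination, total RNA was extracted from liver tissue with a column kit, and libraries were prepared with the Illumina TruSeq RNA kit and pooled for sequencing. The sources used here give neither sex, age, litter, time of collection nor feeding state, and nothing says that the 3 samples of a genotype came from separate animals.

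The deposited values are read counts per gene symbol, 1 file per library, whole numbers with no normalization. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.8b and HTSeq, and the genome builds mm9 and hg19, with no role or order. The HTSeq version, the gene annotation and the strand setting are not given in the sources used here. Each file ends with 5 rows that name no gene, and these were left out of library sizes and tests. Reads outside any gene made up 9.65% to 12.5% of the uniquely placed reads of a library, and reads that fit several genes 0.594% to 0.662%. Alignments of reads placed at several positions numbered 1.49 to 2.65 per gene count. They are not in the gene counts. Genes with near-identical copies, such as the H2, Cyp2, Cyp4, Acot, Gbp and Mup families and the ribosomal proteins, can therefore be counted low, or have reads assigned to the wrong copy. Without a stated strand setting, reads from overlapping genes on opposite strands may not be separated. The rows for low alignment quality and unaligned reads held 0 in each library, so neither quantity can be read from the files.

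The files list 22609 genes, of which 5845 had a count of 0 in all 6 libraries. Gene counts per library ran from 16712568 to 22419411. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the genotype as group and its minimum count of 10, which left 12522. Libraries were scaled by TMM, a quasi-likelihood model with the genotype as its only term was fitted, and 2-sided tests were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of adjusted p under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values come from edgeR's cpm function with TMM-adjusted library sizes. The ratio of Igfbp7 between genotypes has an exact binomial interval of 95%, which covers counting error only, since PCR reads without molecular identifiers are not independent molecules.

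For 41 gene lists fixed before the data were examined, the members past the threshold were counted, adjusted over all genes tested and adjusted over the list alone. The 35 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares a list's genes with all other tested genes. Igfbp7 is in no list. Genes named in the text followed a rule also fixed beforehand. Igfbp7 came first. Among genes past the threshold, those whose 3 knockout values all lay above or all below the 3 wild type values, with a mean of at least 1 CPM and a symbol that is not a predicted or clone name, gave the 10 largest rises and the 10 largest falls, or all of them where fewer passed. Each list gave up to 4 members past the threshold. A list that passed its own test with no member past the threshold gave the 2 members with the lowest p, named as not past it. The sex chromosome genes are given for each library. Genes named outside this rule are said to be chosen after their values were seen.

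Alternatives fixed beforehand were median-ratio, upper-quartile and total-count scaling, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, edgeR with robust estimation, the replicate number as a block, each library left out, counts thinned to the shallowest library, a threshold of 0.01, a minimum absolute log2 fold change of 1, and the tests repeated without the 20 highest genes. For lists they were camera with an estimated correlation, camera on ranks and fry. After the clock genes had been seen to differ between libraries, a clock score (mean log2 CPM of evening-phase genes minus that of morning-phase genes, prior count 2) was added as a covariate, and wild type library 1 and knockout library 2 were left out together. Gene names, overlaps and neighbours were looked up in the RefSeq table of assembly GRCm38.p6, which differs from the builds in the notes, so no coordinates are given.

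The gene test was checked on simulated counts for the knockout comparison, with the real libraries' means, sizes and gene-wise dispersions. Of 12522 genes, 200 were changed, and 199 of these passed the filter. At a fold of 1.5, 20.5% of 73 changed genes were called, at a fold of 2, 75.4% of 65, and at a fold of 4, 98.4% of 61. Of the unchanged genes, 8 were called by edgeR and 24 by DESeq2, which called 137 of the changed genes. No called gene had the wrong sign with edgeR. Within a genotype, library pairs differed by a chi-square of 21.9 to 40.2 per degree of freedom over genes with at least 10 counts, so no library was a copy of another.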

Results

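Gene expression was compared between 3 liver samples of wild type mice and 3 of mice with a deletion of Igfbp7, a secreted binding protein for insulin-like growth factors. The series concerns this gene in liver cancer, and the tissue measured here is adult liver. The libraries held 18497934, 21478524 and 16712568 gene counts in wild type replicates 1 to 3 and 22419411, 18912701 and 19570906 in knockout replicates 1 to 3. In a principal component analysis of log2 CPM, the first component held 38.3% of the variance, with wild type libraries at -28.6, -17.3 and -11.0 and knockout libraries at 14.3, 26.3 and 16.3. Whether the replicates were separate animals is not given in the sources used here, so the p-values refer to the spread between these samples.

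Igfbp7 transcripts were nearly gone from the knockout livers. Wild type libraries held 1438, 1705 and 1055 counts, or 72.4 ± 10.1 CPM (SD, n = 3), and knockout libraries held 5, 2 and 9 counts, or 0.263 ± 0.168 CPM (SD, n = 3). The knockout level was 0.367% of the wild type level (95% exact interval 0.209% to 0.596%, counting error only), a 273-fold difference with bounds of 168 and 478. The log2 fold change was -8.05 ± 0.27 (SE), with an adjusted p of 6.34e-06 by edgeR's quasi-likelihood test. Igfbp7 overlaps Polr2b and Gm34648 in assembly GRCm38.p6, and reads from a shared stretch can be counted for any of them or for none. It lies on chromosome 5, and the list of genes around it holds 17 genes present in the files, none farther than 19 protein-coding genes away in that assembly. Their 12 tested members had a median log2 fold change of 0.06 (camera adjusted p = 0.845), and edgeR called 0 of them over all genes. Clock, a core component of the circadian clock, was the 1 member lower when adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 and 1 called lower by DESeq2.

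Beyond Igfbp7, the genes that rose in the knockout livers included the xenobiotic receptor gene Nr1i3, the steroid hydroxylase gene Cyp17a1 and the lipase inhibitor gene G0s2. Those that fell included the interferon-inducible genes Ifi47, Cxcl9 and Irf7 and the lipoprotein lipase gene Lpl. In all, edgeR called 27 genes of 12522 tested, 16 higher and 11 lower in the knockout. In each of the 27, the 3 knockout values lay entirely above or below the 3 wild type values, which selection at this threshold largely brings with it. Over all tested genes such a separation held for 2598, or 20.7%, where chance gives 10%. Genes that move together are not independent, so this excess is no test. The largest called rise was in Tox, a nuclear protein of lymphocyte development, from 1.51 ± 0.44 to 6.19 ± 1.54 CPM (SD, n = 3 each), a log2 fold change of 2.02 ± 0.27 (SE). Cyp17a1 rose 3.88-fold, from 4.45 to 17.3 CPM on average. G0s2, an inhibitor of adipose triglyceride lipase, rose from 15.3 ± 5.1 to 57.0 ± 3.8 CPM (SD, n = 3 each), a log2 fold change of 1.90 ± 0.22 (SE). Cyp26b1, which degrades retinoic acid, rose 3.25-fold. Por, the electron donor of microsomal cytochromes P450, rose from 185 ± 54 to 569 ± 46 CPM (SD, n = 3 each). Nr1i3, also called CAR, rose 2.52-fold with the smallest p after Igfbp7 (adjusted p = 0.0119, edgeR). Tomm40l rose 2.32-fold, but it overlaps Nr1i3 and Apoa2, the latter at 5653 CPM in wild type and 6209 CPM in knockout livers, in GRCm38.p6, and reads from a shared stretch can be counted for either gene or for none. Pcsk4 rose 3.05-fold, Fbxo31 2.14-fold and Pfkfb1, an enzyme that sets the level of fructose-2,6-bisphosphate, 2.06-fold. Pfkfb1 overlaps Apex2.

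Among the genes that fell, Ddc, the aromatic amino acid decarboxylase, went from 117 ± 19 to 38.6 ± 8.4 CPM (SD, n = 3 each), a log2 fold change of -1.60 ± 0.18 (SE). Ifi47, an interferon-inducible GTPase, had a log2 fold change of -1.26 ± 0.17 (SE) and Cxcl9, a chemokine induced by interferon-gamma, -1.06 ± 0.12 (SE). Lpl fell from 42.2 ± 2.4 to 22.2 ± 1.4 CPM (SD, n = 3 each). Wdfy1, which overlaps Mrpl44, fell to 0.549 of its wild type level, Irf7, a transcription factor of the type I interferon response, to 0.567, and Sdc3, a heparan sulfate proteoglycan, to 0.579. The other 9 called genes fell outside the naming rule and were chosen after their values were seen. C730036E19Rik, a noncoding RNA also known as lncLSTR, rose 2.60-fold, BC024386 2.04-fold, Nrbp2 2.05-fold, Ptp4a1 1.96-fold, Vegfa 1.77-fold and Serpina6, the gene for corticosteroid-binding globulin, 1.74-fold. Kif23, a mitotic kinesin at under 2 CPM in every library, had a log2 fold change of -2.30 ± 0.34 (SE), 2810405K02Rik, also called Prxl2b, -1.41 ± 0.17 (SE), and 1500017E21Rik, also called Hectd2os, -0.84 ± 0.11 (SE). Hectd2os overlaps Hectd2.

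**Figure D1:**
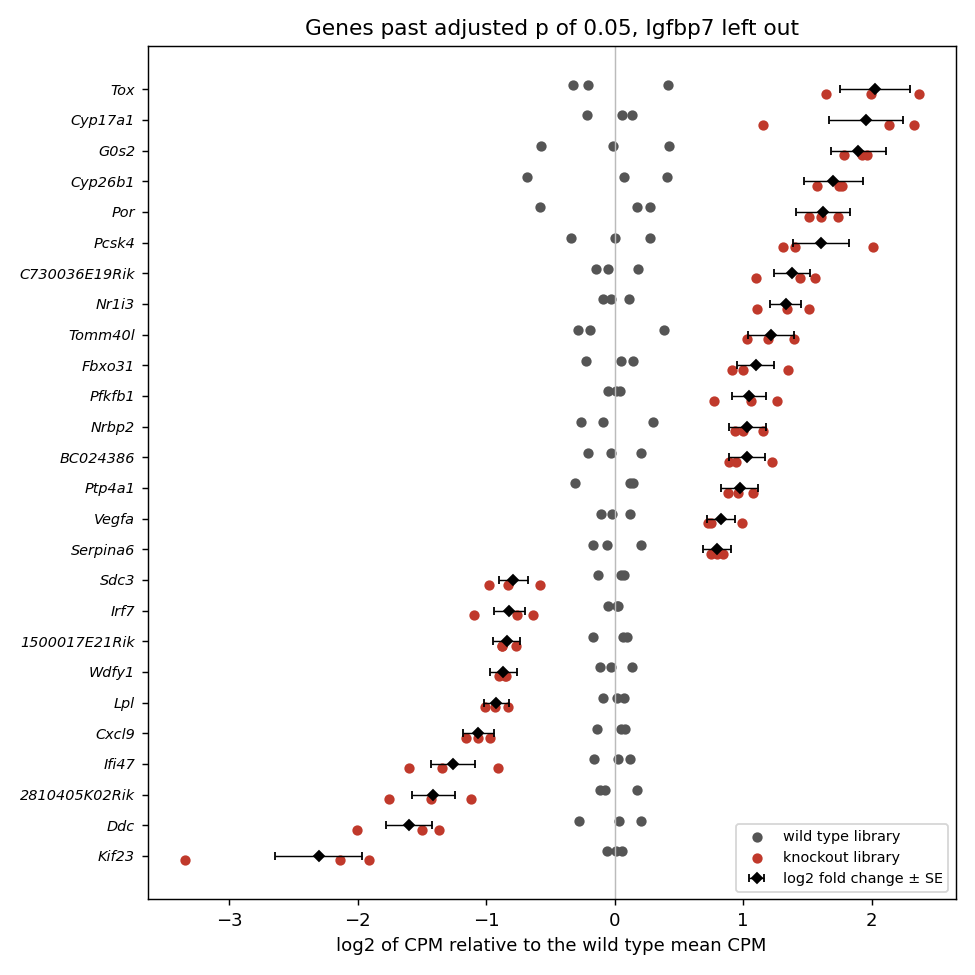
The 26 called genes other than Igfbp7, with the log2 of each library's CPM relative to the wild type mean on the x axis (grey wild type, red knockout, 3 libraries each) and black diamonds for the fitted log2 fold change with its SE. Log2 fold changes ran from -2.30 in Kif23 to 2.02 in Tox, and in each gene the knockout points lay on 1 side of all wild type points.

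Apart from Igfbp7 the adjusted p of these calls ran from 0.0119 to 0.0489, and with 1 library left out the calls, Igfbp7 included, numbered 5 without wild type replicate 1 (5 of them among the 27), 4 without wild type replicate 2 (3), 36 without wild type replicate 3 (18), 20 without knockout replicate 1 (8), 3 without knockout replicate 2 (3) and 13 without knockout replicate 3 (7). Igfbp7 alone was called with a clock score of each library as a covariate, with the replicate block, or without wild type replicate 1 and knockout replicate 2 together, whereas DESeq2 called 435 genes.

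Immune and interferon genes were lower in the knockout livers as lists. Of the 37 tested interferon-stimulated genes 35 were lower, at a median log2 fold change of -0.62 (camera adjusted p = 3.21e-26, and adjusted p = 0.199 with an estimated correlation). Cxcl9, Ifi47 and Irf7 were the 3 that fell over all genes, and 24 were lower when adjusted over the list alone. Kupffer cell and macrophage markers were lower in 22 of 23 members, at a median of -0.64 (camera adjusted p = 3.94e-21, and adjusted p = 0.317 with an estimated correlation). By edgeR 0 of them passed over all genes, 19 were lower when adjusted over the list alone and 19 at an unadjusted p under 0.05, and DESeq2 called 15 lower. C1qb, a subunit of complement C1q made by macrophages, stood at 67.0 ± 7.7 CPM in wild type and 39.8 ± 5.7 CPM in knockout livers (SD, n = 3 each), and Aif1 at 5.87 ± 0.40 and 2.94 ± 0.60 CPM (SD, n = 3 each), neither past the threshold over all genes. The list for MHC class II and dendritic cells was lower in 15 of 16 members, at a median of -0.79 (camera adjusted p = 2.29e-13, and adjusted p = 0.199 with an estimated correlation). The edgeR count over all genes was 0, 10 were lower when adjusted over the list alone and 11 at an unadjusted p under 0.05, and DESeq2 called 7 lower. H2-DMa was at -1.18 ± 0.19 (SE, edgeR adjusted p = 0.0596) and Cd74, the invariant chain, at -1.10 ± 0.19 (SE, edgeR adjusted p = 0.0687).

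MHC class I antigen presentation genes were lower in 18 of 19 members, at a median of -0.28 (camera adjusted p = 1.00e-05, and adjusted p = 0.317 with an estimated correlation). With edgeR, 0 members passed over all genes, 5 were lower when adjusted over the list alone and 7 at an unadjusted p under 0.05, and DESeq2 called 5 lower. H2-D1 was at -0.60 ± 0.12 (SE) and the immunoproteasome subunit Psmb8 at -0.68 ± 0.14 (SE), neither past the threshold over all genes. Markers of T and NK cells were lower in 11 of 12 members, at a median of -0.80 (camera adjusted p = 0.000128, and adjusted p = 0.199 with an estimated correlation). By edgeR 0 passed over all genes, 4 were lower when adjusted over the list alone and 5 at an unadjusted p under 0.05, and DESeq2 called 0. Gzma stood at 1.05 CPM in wild type and 0.378 CPM in knockout livers, not past the threshold over all genes. B and plasma cell markers were lower in 7 of 8 members, at a median of -0.55 (camera adjusted p = 0.0184, and adjusted p = 0.317 with an estimated correlation). Over all genes edgeR called 0, 1 was lower when adjusted over the list alone and 3 at an unadjusted p under 0.05, and DESeq2 called 0. Ms4a1 was at -1.21 ± 0.33 (SE) and Cd79b at -0.61 ± 0.24 (SE). The filter kept 12 of 24 T and NK cell markers and 8 of 13 B and plasma cell markers in the files. It also kept 16 of 20 genes of the MHC class II list. A gene scarce in knockout livers passes the filter only where wild type livers hold more, which can tilt these lists lower. The B cell call was lost without wild type replicate 1 (camera adjusted p = 0.0575), with DESeq2 statistics (adjusted p = 0.0606) and with the clock score (adjusted p = 0.212). The medians were -0.41, -0.55 and -0.29 in that order. Both tested neutrophil markers were lower, at a median of -0.81, too few for a list test. They were the 2 of 14 in the files that passed the filter, so the same tilt can apply.

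Markers of other liver cells gave list medians from -0.44 to 0.10. Liver endothelial markers had a median of -0.07 over 22 members, which was 0.004 without wild type replicate 2 (camera adjusted p = 0.828 with all libraries). The edgeR count over all genes was 0, as was that adjusted over the list alone, 1 was higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 0. Stellate cell and collagen genes had a median of -0.17 over 24 members (camera adjusted p = 0.0188, and adjusted p = 0.534 with an estimated correlation). Adjusted over the list alone or over all genes, edgeR called 0 and 5 were lower at an unadjusted p under 0.05, DESeq2 called 0, and Tgfb1 was at -0.53 ± 0.18 (SE) and Loxl1 at -0.84 ± 0.29 (SE). That call was lost without wild type replicate 1, at a median of -0.05 (camera adjusted p = 0.159), or knockout replicate 1, at -0.10 (camera adjusted p = 0.355), and the median was 0.05 with the clock score as a covariate. Cholangiocyte and progenitor markers were lower in 10 of 11 members, at a median of -0.44 (camera adjusted p = 0.000385, and adjusted p = 0.317 with an estimated correlation). The filter kept these 11 of the 15 in the files, which can tilt the list lower as for T and NK cell markers. By edgeR 0 passed over all genes, 4 were lower at an unadjusted p under 0.05, 1 was lower when adjusted over the list alone, and DESeq2 called 1 lower. Spp1, the gene for osteopontin, was at -0.82 ± 0.13 (SE) and Krt18 at -0.52 ± 0.16 (SE). Genes of hepatocyte identity had a median of 0.10 over 20 members (camera adjusted p = 0.154). The list was called higher without wild type replicate 2, at a median of 0.18 (camera adjusted p = 0.0366), or knockout replicate 3, at 0.14 (camera adjusted p = 0.0186).

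**Figure D2:**
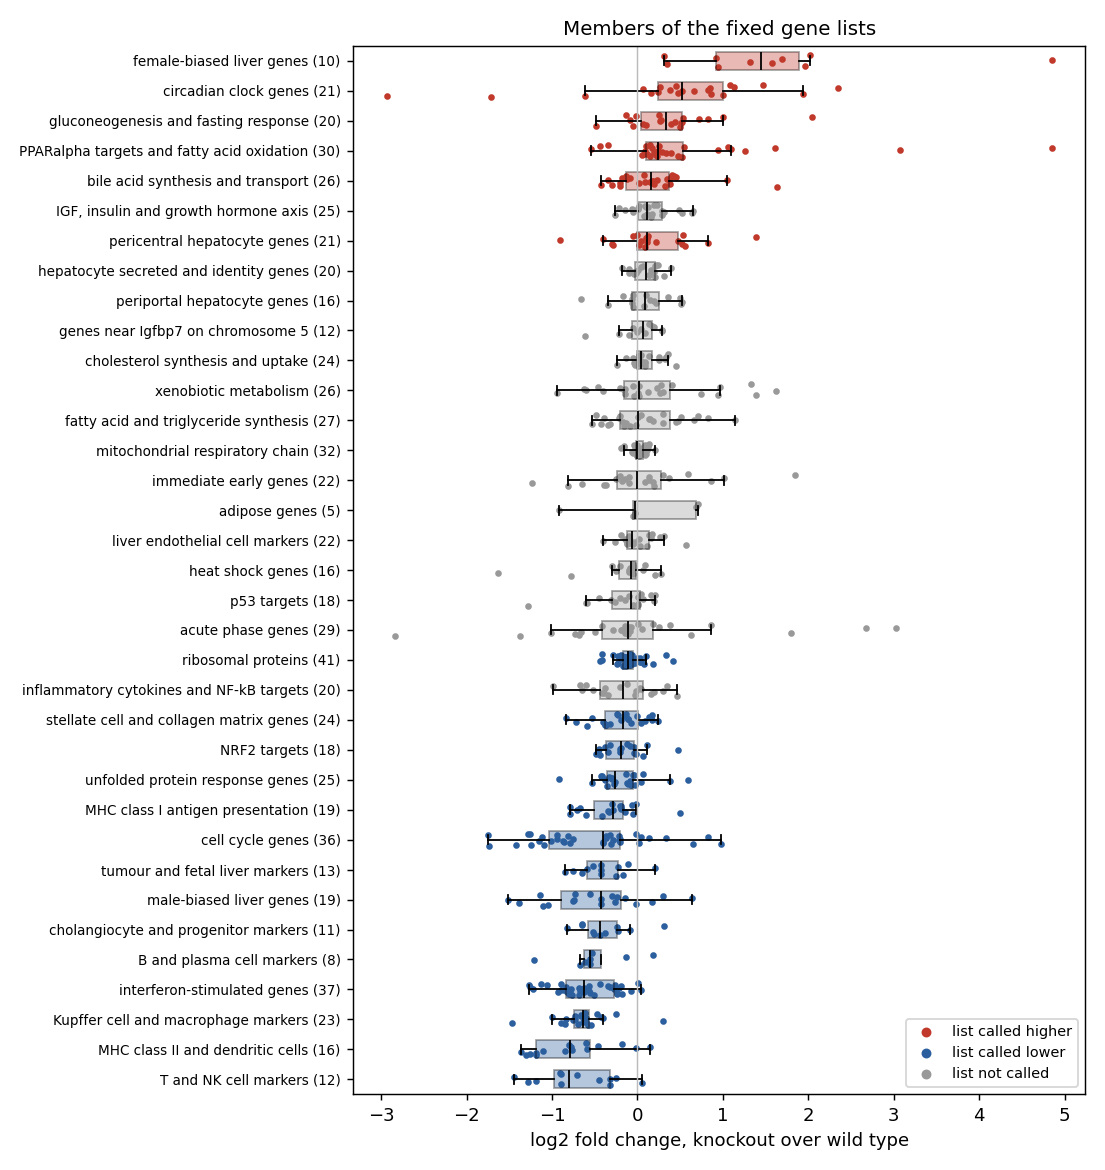
Log2 fold change, knockout over wild type, of each tested member (points) of the 35 tested gene lists, with the number of members in brackets, boxes for the quartiles with the median as a line, and whiskers to the last point within 1.5 box lengths. Colours mark lists called higher (red), called lower (blue) or not called (grey) by camera at the preset correlation, and the medians run from -0.80 in T and NK cell markers to 1.44 in female-biased genes.

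Female-biased liver genes were higher and male-biased liver genes lower in the knockout livers, all of which were male by their transcripts. All 10 tested female-biased genes were higher, at a median log2 fold change of 1.44 (camera adjusted p = 1.46e-09, and adjusted p = 0.248 with an estimated correlation). The filter kept these 10 of the 23 list genes in the files. A gene scarce in wild type livers passes it only where knockout livers hold more, which can tilt the direction and median upward. Tox and Cyp17a1 were the 2 that rose over all genes, and 5 were higher when adjusted over the list alone. Acot3, an acyl-CoA thioesterase, stood at 0.314 ± 0.255 CPM in wild type livers (SD, n = 3) and at 2.46, 3.98 and 22.5 CPM in knockout replicates 1 to 3, a log2 fold change of 4.86 ± 1.03 (SE) that was 3.27 without knockout replicate 3 and did not pass in either case. The list mean relative to wild type was 0.83, 1.04 and 2.18 in knockout replicates 1 to 3, and the median was 0.82 without knockout replicate 3. Male-biased genes were lower in 16 of 19 members, at a median of -0.43 (camera adjusted p = 4.24e-05, and adjusted p = 0.324 with an estimated correlation). Over all genes edgeR called 0, 1 was higher and 7 lower at an unadjusted p under 0.05, 4 were lower when adjusted over the list alone, and DESeq2 called 4 lower. Cyp4a12a, a fatty acid hydroxylase whose close relative Cyp4a12b can share its reads, stood at 314 ± 34 CPM in wild type and 145 ± 38 CPM in knockout livers (SD, n = 3 each), with an edgeR adjusted p of 0.0587. Cyp2u1 was at -0.76 ± 0.15 (SE). Wild type replicate 2 had a mean of -0.42 for the male-biased list, below knockout replicates 1 and 2 at -0.27 and -0.30, and the median was -0.21 without wild type replicate 3.

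The sex of each library was read from counts. Xist, the RNA of the inactive X chromosome, had 1, 2 and 0 counts in wild type and 5, 3 and 3 counts in knockout replicates 1 to 3. In the same order the Y-linked genes had, for Ddx3y, 1613, 2205 and 2067 counts against 2537, 2160 and 2394 counts, for Eif2s3y 1137, 1060 and 1088 against 1597, 1326 and 1441, for Kdm5d 342, 395 and 376 against 490, 521 and 494, and for Uty 324, 408 and 352 against 406, 337 and 368. The 4 tested sex chromosome genes had a median log2 fold change of 0.27, too few for a list test. The edgeR count over all genes was 0, DESeq2 called 0, and Eif2s3y and Kdm5d were the 2 higher when adjusted over the list alone, with 2 higher at an unadjusted p under 0.05.

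The clock genes differed between the genotypes as a list and also among the wild type livers. They were higher in 18 of 21 members, at a median of 0.52 (camera adjusted p = 3.55e-05, and adjusted p = 0.248 with an estimated correlation). With edgeR, 0 members passed over all genes, 3 were higher and 1 lower when adjusted over the list alone, 11 were higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher and 2 lower. Gm129, a repressor of the clock also called Ciart, was at 5.40 ± 4.71 CPM in wild type and 27.3 ± 2.9 CPM in knockout livers (SD, n = 3 each), and Clock at 68.6 ± 13.6 and 44.9 ± 5.8 CPM (SD, n = 3 each). Arntl and Dbp, chosen after their values were seen, set wild type replicate 1 apart. Its level of Arntl, the partner of Clock, was 17.6 CPM, against 2.85 and 2.31 CPM in the other wild type livers and 1.91 to 2.75 CPM in the knockout livers, and its level of Dbp was 10.2 CPM against 51.0 to 78.8 CPM in the other 5 libraries. Without wild type replicate 1 the clock list was still called higher, at a median of 0.40 (camera adjusted p = 2.90e-07). It was called in each of the 6 fits with 1 library left out. The clock score was -0.47, 2.45 and 2.94 in wild type and 3.22, 3.79 and 3.63 in knockout replicates 1 to 3. With this score as a covariate 9 lists in place of 14 were called lower. The calls lost, with medians with and without the score, were those for B and plasma cells (-0.29 and -0.55), stellate cells (0.05 and -0.17), NRF2 targets (-0.11 and -0.19), tumour markers (-0.16 and -0.42) and ribosomal proteins (-0.10 and -0.12). Of the lists called higher the score ended the calls for gluconeogenesis genes, at a median of 0.11 against 0.34 without the score, and bile acid genes, whose median was 0.16 both with and without it, while cholesterol synthesis and immediate early genes were called higher. The clock list itself stayed called with the score, at a median of 0.26 (camera adjusted p = 0.00470). The genes of the score are all members of this list, so that call cannot show a clock difference beyond the score.

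**Figure D3:**
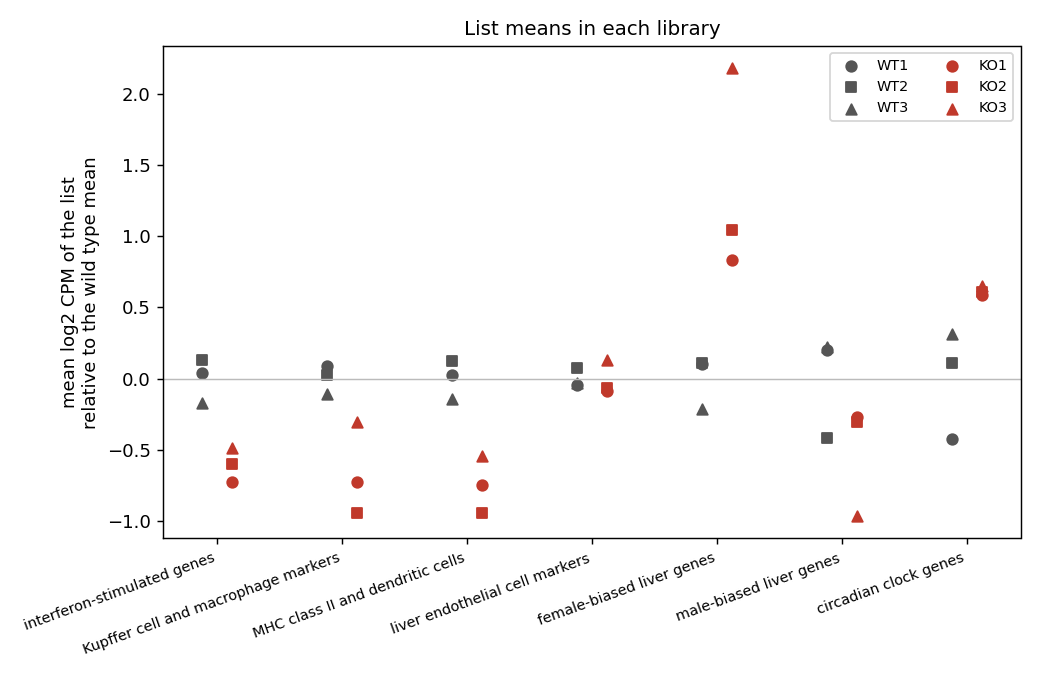
Mean log2 CPM of 7 gene lists in each library relative to the wild type mean (grey wild type, red knockout, symbols for replicates 1 to 3). Kupffer and macrophage markers lay at -0.72, -0.94 and -0.30 in the knockout libraries and endothelial markers at -0.09, -0.07 and 0.13, while knockout replicate 3 lay highest for female-biased genes and wild type replicate 1 lowest for clock genes.

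Genes of fatty acid use and fasting were higher in the knockout livers as lists. PPAR-alpha targets and fatty acid oxidation genes were higher in 27 of 30 members, at a median of 0.24 (camera adjusted p = 1.30e-05, and adjusted p = 0.317 with an estimated correlation). By edgeR 0 passed over all genes, 13 were higher at an unadjusted p under 0.05, 3 were higher when adjusted over the list alone, and DESeq2 called 3 higher. Acot4 was at 1.61 ± 0.32 (SE) and Cpt1a, which carries fatty acids into mitochondria and was chosen after its values were seen, at 0.48 ± 0.12 (SE). The median of PPAR-alpha targets was 0.12 without knockout replicate 1. Gluconeogenesis and fasting genes were higher in 15 of 20 members, at a median of 0.34 (camera adjusted p = 0.000432, and adjusted p = 0.353 with an estimated correlation). Over all genes edgeR called 0, 1 was higher when adjusted over the list alone, 3 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher and 1 lower. Fkbp5, induced by glucocorticoids, stood at 50.1 ± 25.9 CPM in wild type and 207 ± 42 CPM in knockout livers (SD, n = 3 each), with an edgeR adjusted p of 0.0596. G6pc, the last enzyme of glucose release, was at -0.48 ± 0.13 (SE). The median of this list was 0.21 without wild type replicate 1, 0.51 without wild type replicate 2 and 0.19 without knockout replicate 1, and its mean was lower in knockout replicate 2, at 0.23, than in wild type replicate 3, at 0.24. Its call was lost with the clock score as a covariate, at a median of 0.11 (camera adjusted p = 0.652).

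Bile acid genes had a median of 0.16 over 26 members (camera adjusted p = 0.0408, and adjusted p = 0.479 with an estimated correlation). With edgeR, 0 passed over all genes or adjusted over the list alone, 7 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher. Slco1a4 was at 1.05 ± 0.27 (SE) and the sterol transporter gene Abcg5 at 0.45 ± 0.13 (SE). The camera adjusted p was 0.0575 without wild type replicate 1, 0.131 without wild type replicate 3, 0.151 without knockout replicate 1 and 0.208 without knockout replicate 2, and the call was also lost with camera on ranks (adjusted p = 0.0706) and, at an unmoved median of 0.16, with the clock score (adjusted p = 0.0874). The bile acid median was 0.03 without knockout replicate 2 and 0.28 without knockout replicate 3. Pericentral hepatocyte genes had a median of 0.11 over 21 members (camera adjusted p = 0.0278, and adjusted p = 0.494 with an estimated correlation). With edgeR, 0 members passed over all genes, 6 were higher and 1 lower at an unadjusted p under 0.05, 4 were higher when adjusted over the list alone, and DESeq2 called 4 higher. Notum, a feedback inhibitor of Wnt signalling, was at 0.54 ± 0.09 (SE) and Slc1a2 at 0.48 ± 0.12 (SE). Without knockout replicate 2 the pericentral median was -0.07 (camera adjusted p = 0.514), and without wild type replicate 3 it was 0.02 (camera adjusted p = 0.243), while it was 0.19 without wild type replicate 1 and 0.19 without knockout replicate 1. The pericentral call was also lost without the 20 highest genes (adjusted p = 0.0569) and with camera on ranks (adjusted p = 0.0927). Periportal genes had a median of 0.09 over 16 members (camera adjusted p = 0.451), with 1 higher and 1 lower when adjusted over the list alone. They were called higher without wild type replicate 2, at a median of 0.19 (camera adjusted p = 0.0341).

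Xenobiotic metabolism genes went both ways. Of 26 members Nr1i3 and Por were the 2 that rose over all genes, and 5 were higher and 4 lower when adjusted over the list alone. The median was 0.02 (camera adjusted p = 0.0533), and it was -0.02 with upper-quartile and -0.04 with total-count scaling and -0.07 without knockout replicate 2. The list was called higher without wild type replicate 2 (camera adjusted p = 0.00847), knockout replicate 1 (camera adjusted p = 0.0116) or knockout replicate 3 (camera adjusted p = 0.0359), at medians of 0.09, 0.08 and 0.19. The test was also past its threshold, for higher, with upper-quartile scaling (adjusted p = 0.0401), total-count scaling (adjusted p = 0.0479), the replicate block (adjusted p = 0.0233), thinned counts (adjusted p = 0.0405) and DESeq2 statistics (adjusted p = 0.0362).

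Cell cycle genes were lower in 29 of 36 members, at a median of -0.40 (camera adjusted p = 1.21e-05, and adjusted p = 0.324 with an estimated correlation). By edgeR 0 passed over all genes, 2 were higher and 14 lower at an unadjusted p under 0.05, 1 was higher and 3 lower when adjusted over the list alone, and DESeq2 called 1 higher and 3 lower. Mcm6, a subunit of the replicative helicase, stood at 8.86 ± 0.31 CPM in wild type and 4.60 ± 1.45 CPM in knockout livers (SD, n = 3 each), whereas Tk1, thymidine kinase, stood at 11.2 ± 0.5 and 19.9 ± 3.8 CPM (SD, n = 3 each). The cell cycle list mean relative to wild type was -0.67, -0.78 and -0.13 in knockout replicates 1 to 3, the last above wild type replicate 3 at -0.15, and the median was -0.76 without knockout replicate 3. Unfolded protein response genes were lower in 21 of 25 members, at a median of -0.26 (camera adjusted p = 0.000453, and adjusted p = 0.344 with an estimated correlation). Over all genes edgeR called 0, 2 were lower when adjusted over the list alone and 11 at an unadjusted p under 0.05, and DESeq2 called 3 lower. Sdf2l1 was at -0.92 ± 0.21 (SE) and Manf at -0.42 ± 0.10 (SE). The list mean was -0.11, -0.04 and -0.41 in knockout replicates 1 to 3, with the first pair above wild type replicate 2 at -0.12, and the median was -0.16 without knockout replicate 3. Markers of liver tumours and fetal liver were lower in 12 of 13 members, at a median of -0.42 (camera adjusted p = 0.0108, and adjusted p = 0.317 with an estimated correlation). The filter kept these 13 of the 20 list genes in the files, which can tilt the list lower as for T and NK cell markers. With edgeR, 0 passed over all genes or adjusted over the list alone and 2 were lower at an unadjusted p under 0.05, DESeq2 called 0, and Akr1b8 was at -0.76 ± 0.25 (SE) and Cd24a at -0.65 ± 0.27 (SE). The tumour marker call was lost without wild type replicate 1, at a median of -0.25 (camera adjusted p = 0.0968), or knockout replicate 1 (camera adjusted p = 0.0646).

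NRF2 targets were lower in 15 of 18 members, at a median of -0.19 (camera adjusted p = 0.0434, and adjusted p = 0.437 with an estimated correlation). Adjusted over the list alone or over all genes, edgeR called 0, 1 was higher and 3 lower at an unadjusted p under 0.05, DESeq2 called 0, and Hmox1 was at -0.48 ± 0.16 (SE) and Pgd at -0.45 ± 0.16 (SE). The camera adjusted p was 0.0590 without wild type replicate 1, 0.0937 without wild type replicate 2, 0.231 without knockout replicate 2 and 0.0961 without knockout replicate 3, with a median of -0.13 in each of the last pair, and 0.0565 after thinning. Ribosomal protein genes were lower in 33 of 41 members, at a median of -0.12 (camera adjusted p = 0.0389, and adjusted p = 0.317 with an estimated correlation). With edgeR, 0 passed over all genes or adjusted over the list alone and 1 was lower at an unadjusted p under 0.05, DESeq2 called 0, and Rplp1 was at -0.28 ± 0.09 (SE) and Rps20 at -0.18 ± 0.08 (SE). Their camera adjusted p was 0.0575 without wild type replicate 1, 0.0937 without wild type replicate 3, 0.0694 without knockout replicate 2 and 0.182 without knockout replicate 3.

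The remaining lists were not called in the planned test, and some were called in other settings. The IGF, insulin and growth hormone axis had a median of 0.11 over 25 members (camera adjusted p = 0.0597) and was called higher without wild type replicate 2 (adjusted p = 0.0309) or knockout replicate 3 (adjusted p = 0.0378), without a filter (adjusted p = 0.0443), after thinning (adjusted p = 0.0487), with DESeq2 statistics (adjusted p = 0.0438), with limma-voom (adjusted p = 0.0465) and with camera on ranks (adjusted p = 0.0184). Inflammatory cytokines and NF-kB targets had a median of -0.16 over 20 members (camera adjusted p = 0.0501) and were called lower without wild type replicate 2 (adjusted p = 0.00106), wild type replicate 3 (adjusted p = 0.0324), knockout replicate 2 (adjusted p = 0.0332) or knockout replicate 3 (adjusted p = 0.00120). The medians were -0.23, -0.24, -0.20 and -0.46 in that order. That list was also called with median-ratio scaling (adjusted p = 0.0487), without a filter (adjusted p = 0.0242), with the CPM filter (adjusted p = 0.0486), with the replicate block (adjusted p = 0.0423) and after thinning (adjusted p = 0.0351). Cholesterol synthesis genes had a median of 0.04, which was -0.01 with upper-quartile and total-count scaling (camera adjusted p = 0.121). Without wild type replicate 1 it was 0.28 (adjusted p = 4.40e-08), without knockout replicate 2 it was 0.16 (adjusted p = 0.00741), and with the clock score it was 0.42 (adjusted p = 3.45e-18). Fatty acid synthesis genes had a median of 0.01, which was -0.03 with upper-quartile and -0.04 with total-count scaling (camera adjusted p = 0.576), and were called higher without knockout replicate 2 (adjusted p = 0.0495). Immediate early genes had a median of -0.01 and a mean of 0.06 (camera adjusted p = 0.576), and a median of 0.22 without wild type replicate 1 (adjusted p = 0.0232). Acute phase genes had a median of -0.11 and a mean of 0.003 (camera adjusted p = 0.234). They were called lower without wild type replicate 2, at a median of -0.18 (adjusted p = 0.00433), or knockout replicate 2, at -0.26 (adjusted p = 0.0194). Heat shock genes had a median of -0.07 (camera adjusted p = 0.121) and were called lower without knockout replicate 3, at a median of -0.17 (adjusted p = 0.00222).

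The p53 targets had a median of -0.07 (camera adjusted p = 0.251), which was 0.06 without wild type replicate 1. Mitochondrial respiratory chain genes had a median of -0.001, whose sign turned with median-ratio scaling, and a mean of 0.01 (camera adjusted p = 0.725). The 5 adipose genes had a median of -0.03 and a mean of 0.08 (camera adjusted p = 0.828), and Lpl was the 1 that fell over all genes, with 2 higher and 1 lower when adjusted over the list alone. In the other lists of this group edgeR called 0 over all genes. Adjusted over the list alone 1 acute phase gene was higher, Mt1, and 1 heat shock gene lower, Hspb1, both chosen after their values were seen. DESeq2 called 2 fatty acid synthesis genes, 1 cholesterol synthesis gene, 1 immediate early gene and 2 acute phase genes higher, and 3 acute phase genes and 1 heat shock gene lower. Lists with too few members for a test had medians of -0.26 over 4 blood and erythroid genes and 0.12 over 4 platelet genes. At an unadjusted p under 0.05 by edgeR, 2 of these blood genes were lower and 1 platelet gene was higher. The globin genes of the list held 0 counts in every library, so blood content can hardly be read from it. The single tested members for exocrine pancreas and skeletal muscle were at 0.30 and -0.11.

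By camera with the preset correlation 20 of the 35 lists were called, 6 higher and 14 lower, with 9 lower without wild type replicate 1 and 10 higher without wild type replicate 2. The list means of the knockout libraries lay apart from those of the wild type libraries in 10 of the 20, and they overlapped in the other 10, those for stellate cells, cholangiocytes, pericentral genes, cell cycle, gluconeogenesis, bile acids, NRF2 targets, male-biased genes, unfolded protein response and tumour markers. With an estimated correlation 0 were called, the smallest adjusted p being 0.199 and 5 lists having an unadjusted p under 0.05. Fry, which tests whether a list's genes move 1 way on balance, called 0, with 12 lists at an unadjusted p under 0.05.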

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

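Reads outside any gene, which no comparison uses, took a larger share of the uniquely placed reads in each knockout library than in any wild type library. The shares were 11.3%, 12.3% and 12.5% in knockout and 10.7%, 9.65% and 11.3% in wild type replicates 1 to 3, and the lowest knockout share lay above the highest wild type share by less than the spread within either genotype. Among 3 against 3 samples, chance gives such a separation in 10% of cases.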

How the results depend on the processing

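The clock score and the joint omission of wild type replicate 1 and knockout replicate 2 were chosen after the data were seen, and the other settings before. Igfbp7 kept its direction and its call in each setting that refitted the genes, with log2 fold changes from -8.62 to -7.68. All 27 called genes kept their sign in these settings. Their number was 27 with median-ratio, 28 with upper-quartile and 21 with total-count scaling (10 higher), 21 with the CPM filter, 26 after thinning, 27 without the highest genes and 25 with limma-voom. Unfiltered data gave 133 calls (70 higher, 63 lower), robust estimation 68 (38 higher, 30 lower) and DESeq2 435 (241 higher, 194 lower), each including all 27; the cause was not tested. The adjusted p threshold of 0.01 left 1 (0 higher, 1 lower), and 19 passed with an absolute log2 fold change of at least 1 (13 higher, 6 lower). The clock score covariate left 1 (0 higher, 1 lower; 929 genes at an unadjusted p under 0.05), as did the joint omission (0 higher, 1 lower; 1240 genes), in both cases Igfbp7. Leaving out 1 library gave 3 to 36 calls, 1 to 19 higher and 1 to 17 lower, and only Igfbp7 was called in all 6 of these fits. These fits and the covariate have fewer residual degrees of freedom, and the cause of each loss was not tested further.

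The replicate numbers gave no sign of pairs, since same-numbered libraries had correlations of deviations of -0.083, -0.098 and -0.041. The largest correlations were 0.125 for wild type replicate 1 with knockout replicate 2, 0.106 for wild type 2 with knockout 3 and 0.090 for wild type 3 with knockout 1. Whether these mark another pairing or a shared batch was not tested. With the replicate block 1 gene was called (0 higher, 1 lower; 1804 at an unadjusted p under 0.05) and 22 lists; the cause was not tested.

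Camera at the preset correlation called 15 to 25 of the 35 lists over the settings. Estimated correlation gave 0 (0 higher, 0 lower) and fry 0 (0 higher, 0 lower), and camera on ranks 19. Fry also tests another hypothesis than camera, and the cause of its losses was not tested. Leaving out 1 library gave 16 to 25 lists, 4 to 10 higher and 9 to 15 lower, and 13 of the 20 lists were called in each of the 6 fits. Lists called lower numbered 9 with the clock score covariate and 9 with the joint omission, and each of these settings kept 13 of the 20 lists. Over all settings, the 71 single genes followed (named, called, or chosen after their values were seen) came past the threshold 52 times and lost it 215 times, and lists 39 and 78 times. No list's test turned from one called direction to the other, while the stellate median was 0.05 with the clock score and the pericentral median -0.07 without knockout replicate 2, both uncalled there. At the real depth and 3 replicates, 20.5% of genes simulated with a 1.5-fold change were called. Thinning left 26 calls. It only brought libraries of up to 22419411 gene counts to the 16712568 of the shallowest, so it cannot show whether depth is the limit.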

Other observations

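The tests in this part other than the splits of the libraries were chosen after the results were seen. The genes named in this part, other than Igfbp7, Nr1i3 and the sex chromosome genes, were also chosen after their values were seen, and those given first did not pass by edgeR. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, were at 4.25, 4.12 and 4.79 CPM and at 1.22, 1.08 and 1.15 CPM in wild type replicates 1 to 3. In knockout replicates 1 to 3 Mt1 was at 9.47, 51.8 and 22.9 CPM and Mt2 at 1.56, 21.7 and 5.16 CPM, with log2 fold changes of 2.67 ± 0.53 and 3.03 ± 0.86 (SE, edgeR adjusted p = 0.0825 and 0.157, DESeq2 adjusted p = 0.00471 and 0.0588). Cyp2a5, a coumarin hydroxylase, was at 152 to 282 CPM in wild type and at 289, 965 and 499 CPM in knockout livers (edgeR adjusted p = 0.166). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 65.4, 223 and 66.6 CPM in wild type and at 140, 245 and 719 CPM in knockout livers (edgeR adjusted p = 0.281). Nr1i3 rose, while Cyp2b10, a target gene of that receptor, stood at 0.755 ± 0.496 CPM in wild type and 1.28 ± 0.61 CPM in knockout livers (SD, n = 3 each), with an edgeR adjusted p of 0.554. This is 1 gene near the floor, in a family that can be counted low, so it does not speak for the receptor's targets as a set.

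The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The genotype split called 27 genes and the highest of the other splits 0, with 239 to 745 genes at an unadjusted p under 0.05, so 1 split of 10 reached that count. Every other split has both genotypes on each side, so a genotype difference adds to the spread within its sides. Their counts are therefore no measure of what chance alone gives. For lists at the preset correlation the genotype split called 20, the highest of the other splits 17 and the lowest 10, and 1 split of 10 reached 20. The test at the preset correlation thus called many lists even where the genotypes were mixed. None of the splits puts equal numbers of a genotype on both sides, so part of any genotype difference stays between the sides. These list counts therefore do not show what the test calls without a genotype difference.

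The lower immune and interferon genes could reflect the number of immune cells in each sample. A loss of non-parenchymal cells of every kind is argued against by the endothelial markers, with a median of -0.067 and quartiles of -0.12 and 0.14, above the upper quartile of the Kupffer and macrophage markers, -0.56. Fewer Kupffer cells and macrophages stay open, as do lower levels in each cell: 95.7% of the 23 markers were lower, among them the abundant Cd5l at 181 and 100 CPM and Clec4f at 177 and 121 CPM in wild type and knockout livers, but that share is the pattern itself and decides between neither. Collection time stays open too. The median over 115 members of the 6 immune lists was -0.61 without the clock score (quartiles -0.83 and -0.29) and -0.54 with it (quartiles -0.80 and -0.24). A single wild type library mostly sets the score, so this kept median cannot decide on collection time. The genotype, the housing or infection history of the mice, and the cells in which interferon genes differ stay open.

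The clock genes may differ because the livers were collected at different times of day. The median of 11 evening genes was 0.86 and that of 5 morning genes -0.61, a difference of 1.47 with the opposite directions that different times would give, although Cry1 and Nfil3 among the morning genes were not lower. Wild type replicate 1 had a clock score of -0.47 against 2.45 and 2.94 in the other wild type livers. The clock list kept a median of 0.26 with the score in the model. The score was made from members of that list, and a median over genes that move both ways cannot show how much of the difference the score takes up. An effect of the genotype or of feeding on the clock stays open. For the 27 called genes collection time stays open too: the median ratio of the log2 fold change with the score to that without it was 0.94 (quartiles 0.85 and 1.003), but genes called for a small spread within a genotype can hardly follow a score set by a single wild type library. All their calls but that of Igfbp7 ended with the score, when the standard error was 1.33 times as large at the median and 3 residual degrees of freedom remained in place of 4.

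The higher female-biased and lower male-biased genes do not come from female livers, since the highest Xist count of a knockout library was 5 and the lowest count of a Y-linked gene 337. With the sign of the male-biased genes turned, the median over both lists was 0.74 (quartiles 0.29 and 1.32). It was 0.63 with the clock score (quartiles 0.20 and 1.17). That cannot decide on collection time, since a single wild type library mostly sets the score. Members with symbols starting with Cyp, Mup, Ugt, Sult, Hsd3b, Acot, Slco, Serpina, Cml, Gst or Akr were then removed to leave out multi-copy families. The removal went by prefix alone, whether or not a gene has close copies. Over the remaining 13 the signed median was 1.14 (quartiles 0.32 and 1.51). Most genes outside these prefixes thus moved in the same directions. The female-biased ones among them passed a filter that can tilt their values upward, so this median cannot decide on reads shared within families. Members of other families can remain among the 13. An effect of the genotype stays open and untested.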
